A study of Gossypium hirsutum with 3 samples.

How the data were processed

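Small RNA libraries from cotton leaves were analysed from the deposited files, 1 per library, each listing every distinct sequence with its length and read count. Per the labels, the plants were of cultivar SN-011 and precultured for 10 d, and each group had 1 sample. The values are raw read counts that the authors deposited after removing adapters and low-quality reads, per the series' design text; the tools and versions of that step are not given in the sources used here. The totals of the files equal the clean read totals the submitters state, so that scaling to the stated totals changes nothing. Sequences were 18 to 44 nt long. No value in the files was normalised, and no alignment was used.

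RPM values were computed here as reads per 1000000 reads of the file total. Lengths were taken as listed, with reads of 18 to 30 nt as the denominator of shares, and shares have exact Clopper-Pearson 95% intervals. A miRNA family was the sum of reads of 19 to 24 nt whose bases 1 to 18 matched a listed mature sequence with at most 1 mismatch, each read going to its best family. Isoforms with a shifted 5′ end were therefore not counted. Among them were a miR156 form with 115502, 154695 and 116216 reads in the control, 4 h and 5 d libraries, and a miR166 form with 59277, 61029 and 59497. The list held 67 mature sequences of 39 families in 10 groups, 16 passenger strands, TAS3 tasiRNAs and 10 background miRNAs of other organisms. Related families, such as miR156 and miR157 or miR165 and miR166, were counted together by choice. The leading miR157 and miR156 sequences differ within bases 1 to 18 and are also given singly.

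A log2 ratio between libraries has an exact conditional binomial 95% interval, and a family was counted as higher or lower at 2-fold with at least 100 reads over the 2 libraries. No test was possible with 1 library per group, and no p-value is given. Group medians used families with at least 10 reads, beside 10000 random lists drawn from 20 to 22 nt sequences among the nearest 100 in abundance. Distinct sequences were compared at 50 RPM or more in either library, with a count of 0.5 in place of 0.

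The families named were, for each salt library against control, the 8 with most reads and 15 more with the largest ratios, and for the salt libraries against each other the 5 with the largest. The sequences named were the 5 highest and 5 lowest ratios among those with at least 200 RPM. Members of a group could be given as its examples. The rRNA classes and the sequences in the closing observations outside this rule were chosen after their values were seen.

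Fragments of tRNA, rRNA and U6 were exact substrings of 10 sequences listed beforehand. These were extended after the data were seen with 14 rRNA seeds, lengthened over the reads by 17-base words with at least 5 reads, and 3 tRNA parts. Several seeds, among them the last 2, were taken from sequences with extreme ratios at 4 h, so the rRNA class is partly chosen by outcome, and sizes within it are also given without those seeds, without 5.8S rRNA and for the listed sequences alone. A sequence was called a 1-base variant when a sequence with at least 10-fold its reads differed from it at 1 base.

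The matching and ratios were tested on simulated data. All 1340 simulated reads with 1 mismatch were assigned to their own family, and 1 of 1340 with 3 mismatches was. In simulated counts for the 1191 sequences of the 4 h comparison with 200 of them altered, 100% of those altered 4-fold and 0% of those altered 1.5-fold were counted at 2-fold, as were 0 of the 991 others, and the 95% intervals held the true value for 95.6%. For the 1019 sequences of the 5 d comparison the intervals held it for 96.0%. The simulated counts varied by counting error alone, so they check the calculation and give no rate of false calls between single libraries.

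Alternatives covered the scaling, the matching rule, the minimum count, the size of the ratio and the removal of the 10 most abundant sequences. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genome positions and hairpin precursors were not analysed here, since no reference genome was used. The sequences found almost only in the 5 d library are not printed, as their organism was not determined.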

Results

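Small RNAs were sequenced from leaves of upland cotton (Gossypium hirsutum) cultivar SN-011 to compare the small RNA populations of seedlings kept without salt and seedlings exposed to 150 mM NaCl. The 3 libraries came from 1 control sample, 1 sample taken after 4 h of salt and 1 sample taken after 5 d of salt. The 4 h seedlings received 150 mM NaCl at once, whereas the salt of the 5 d seedlings was raised in steps of 50 mM every 12 h, so duration and mode of application differed together. No sampling time is given for the control, so seedling age may also differ between the libraries. The control, 4 h and 5 d libraries held 17026070, 15731477 and 22590391 reads, spread over 4331028, 3003594 and 6102868 distinct sequences. There were no replicates, so each comparison is between libraries rather than conditions, no test between groups could be made, and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A count of 3 reads, the floor used here, equals 0.176, 0.191 and 0.133 RPM (reads per 1000000 reads of the file) in the 3 libraries.

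The 21-nt and 24-nt classes dominated every library, the former being the usual length of miRNAs and the latter that of heterochromatic siRNAs. The 24-nt class held 25.4% of the 18 to 30 nt reads in control, 13.7% at 4 h and 26.98% at 5 d. The 21-nt class held 41.4%, 51.8% and 36.7%, so the ratio of 24-nt to 21-nt reads was 0.613, 0.265 and 0.734. The exact binomial 95% intervals of the 24-nt shares were 25.35% to 25.39%, 13.72% to 13.75% and 26.96% to 26.99%. Reads of 18 and 19 nt made up 5.70% of the control library, 9.90% at 4 h and 5.43% at 5 d. Adenine was the 5′ base of 58.2%, 56.4% and 55.8% of the 24-nt reads, and uracil that of 82.5%, 84.5% and 80.1% of the 21-nt reads.

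**Figure D1:**
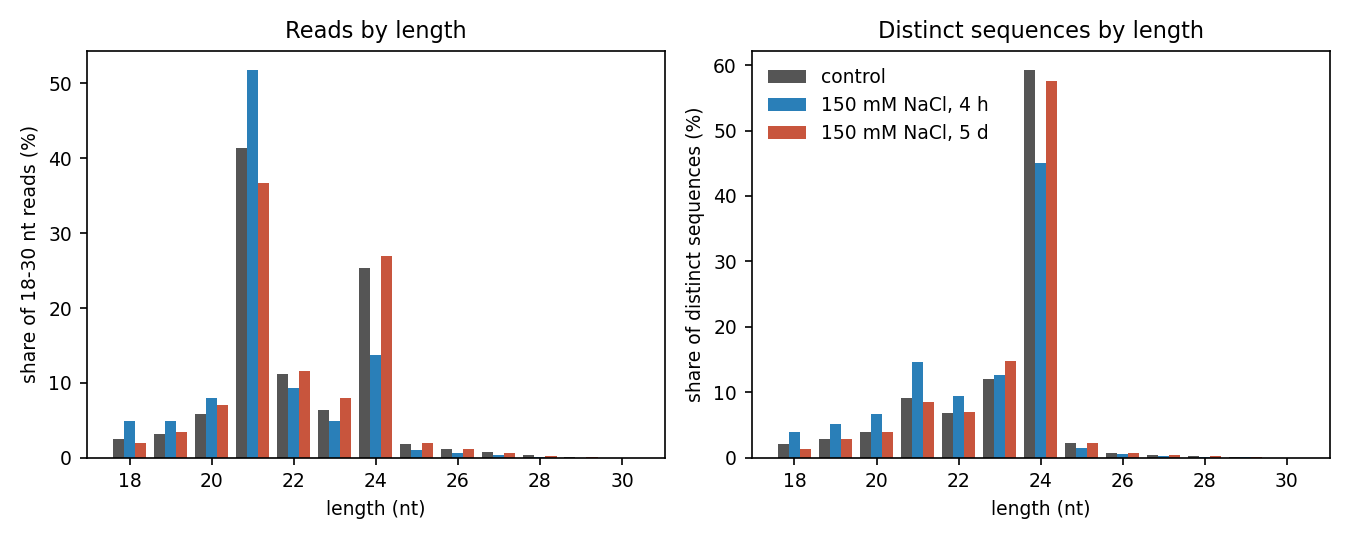
Length distribution of small RNAs, with length in nt on the x axis and the share in % on the y axis, for 18 to 30 nt reads on the left and distinct sequences on the right; each bar is 1 library. The 24-nt bar is lowest at 4 h in both panels, with 13.7% of reads and 45.0% of distinct sequences.

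The fragments of rRNA, tRNA and U6 snRNA, taken as signs of RNA quality, also differed between libraries. Fragments of rRNA, a class partly chosen by outcome, made up 7.66% of the reads in control, 9.17% at 4 h and 7.78% at 5 d. The sum of the rRNA listed beforehand went the other way at 4 h, with 220119 reads in control and 147067 at 4 h, but only its 5.8S rRNA was lower. Fragments of tRNA made up 2.34%, 1.51% and 1.57%. The 18 and 19 nt share of rRNA fragments was 18.9% in control, 35.3% at 4 h and 16.998% at 5 d, and that of tRNA fragments 36.2%, 62.8% and 40.4%. Fragments of 5.8S rRNA were at 18942, 6659 and 10591 RPM, whereas those of 25S rRNA were at 36664, 55696 and 40656. In the sequences listed beforehand, 5.8S rRNA was at 11419, 3621 and 7043 RPM. The listed 18S part was at 957, 4215 and 3573 RPM and the listed 5S rRNA at 552, 1512 and 1286. The listed 25S fragment had only 4, 5 and 2 reads, so the 25S values rest on the seeds added after the data were seen. U6 fragments were at 54.3, 54.9 and 64.9 RPM.

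Reads of the 39 listed miRNA families made up 35.1% of the control library, 42.1% of the 4 h library and 31.8% of the 5 d library, and each family had at least 1 read in every library. At the floor of 3 reads or more there were 37, 39 and 37 families, miR479 and miR828 being under it in control and at 5 d. The miR156/miR157 family, which targets SPL transcription factors of phase change, was the most abundant, with 268281 RPM in control, 352860 at 4 h and 230112 at 5 d. Its miR157 sequence TTGACAGAAGATAGAGAGCAC alone accounted for 24.3%, 31.8% and 19.9% of all reads. The miR3954 family followed with 46154, 28004 and 44291 RPM, and the miR165/miR166 family, which targets HD-ZIP III leaf polarity genes, with 16909, 17652 and 24782. The miR167, miR164, miR535, miR168 and miR3476 families were at 7138, 3887, 3057, 2150 and 816.7 RPM in control.

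After 4 h of salt, the family furthest from control among those with at least 100 reads over the 2 libraries was miR390, which triggers the production of TAS3 tasiRNAs against auxin response factors. It was at 556.1 RPM in control and 112 at 4 h, 4.97-fold lower (log2 ratio -2.31, 95% interval -2.39 to -2.24), and it stayed at least 2-fold lower under every alternative scaling, matching rule and minimum count. Its passenger strand was 2.10-fold lower, while the TAS3 tasiRNAs were at 785 RPM in control and 806 at 4 h. miR477 was 2.08-fold higher (log2 ratio 1.06, 95% interval 0.87 to 1.25), and with at most 2 mismatches its ratio was 0.89. These were the only families at least 2-fold apart among the 31 with at least 100 reads.

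The median log2 ratio of the families at 4 h was 0.41 over the 27 families with at least 100 reads in each library, so that 25 of 31 ratios were above 0. Relative to that median, 0 families were at least 2-fold higher and 4 were lower, namely miR390 (-2.72), miR168 (-1.25), miR397 (-1.20) and miR3954 (-1.13), against 1 higher and 1 lower when scaled to the file total. miR477 was then at 0.65. Under the same centring miR156/miR157 went from a log2 ratio of 0.40 to -0.01, miR535 from 0.30 to -0.11, miR167 from 0.09 to -0.32 and miR165/miR166 from 0.06 to -0.35, so no direction is given for these. The miR3954 ratio of -0.72 turned to 0.45 when only exact matches to the listed sequence were counted, although its leading cotton sequence TTGGACAGAGTAATCACGGTCG, with 98.1% of its reads, had a ratio of -0.73.

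The group medians at 4 h are scaled to the file total, and those by the median of ratios are called centred. Among the families of small RNA machinery, 3 of 3 were within 2-fold at 4 h, with a median log2 ratio of 0.51 (centred 0.10), although miR168 was at -1.25 when centred. miR168, which targets ARGONAUTE1, had a log2 ratio of -0.84 and its passenger strand one of 0.80, from 63.8 to 111 RPM. miR162, which targets DICER-LIKE1, was at 0.76 and miR403, which targets ARGONAUTE2, at 0.51. All 8 measured families of phase and leaf development were within 2-fold, with a median of 0.38 (centred -0.03); miR172 was at 0.36 and miR164 at 0.42. In the auxin group 2 of 4 families were at least 2-fold lower, with a median of -0.74 (centred -1.15) at percentile 7.55 of random lists matched on abundance. These were miR390 and miR393, the latter with 45 reads in control and 14 at 4 h, and without families under 100 reads the median was 0.09; miR160 was at 0.71.

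Of the 3 copper families, which target laccases, plantacyanins and superoxide dismutases, 1 was at least 2-fold lower at 4 h and the group median of -0.80 (centred -1.20) lay at percentile 2.12, but was -0.21 without families under 100 reads and -0.21 with exact matches. miR398 had 34 reads in control and 4 at 4 h (log2 ratio -2.97, 95% interval -4.93 to -1.49), miR397 had a ratio of -0.80 and miR408 one of 0.38. The 4 phosphate and sulphate families were all within 2-fold, with a median of 0.49 (centred 0.08) at percentile 80.4; miR827 was at 0.59 and miR399 at -0.38. In the NF-Y and F-box group 1 of 3 families, miR393, was at least 2-fold lower, and the median was 0.07 (centred -0.34). The MYB group had 1 of 2 measured families higher, miR858 with 22 and 57 reads, and a median of 0.83 (centred 0.42), which was 0.17 without families under 100 reads and 0.15 with exact matches. All 7 families of cotton and near relatives were within 2-fold, with a median of 0.44 (centred 0.03), and the largest was miR3476 at 0.81, while miR3954 was at -1.13 when centred. Of the other conserved families 1 of 3, miR477, was higher, with a median of 0.95 (centred 0.55) at percentile 94.98. The family that targets disease resistance genes, miR472/miR482/miR2118, was at 0.49 (centred 0.08).

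Among 1191 distinct sequences with at least 50 RPM in either library, 415 were at least 2-fold higher at 4 h and 220 lower. Fragments of rRNA made up 418 of these sequences, of which 213 were higher and 85 lower, counts that depend on seeds partly picked by their 4 h ratios. The lowest ratios belonged to 5.8S rRNA fragments and a tRNA-Trp fragment. AACGACTCTCGGCAACGGATATCT was 30.4-fold lower, AGAACGACTCTCGGCAACGGATAT 27.9-fold, AGAACGACTCTCGGCAACGGATATC 26.7-fold, AGAACGACTCTCGGCAACGGATATCT 24.02-fold and the tRNA fragment CGTTTCACGTCGGGTTCACCA 23.7-fold. The highest were TCGTTCGTCTGACTTGGG, in none of the sets used here and 39.1-fold higher, the 25S fragment GCAGGACGGTGGTCATGG (29.2-fold), TCGTAGGTGCAGCGGCCGCGGCG, also in none of the sets (23.1-fold), the 25S fragment TGAGAACTTTGAAGGCCGAAGAGGGG (21.3-fold) and the 18S fragment GACTGTGAAACTGCGAATGGCTC (18.8-fold). No reference genome was used here, so genome positions of these sequences were not analysed.

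After 5 d of salt, the families of copper and of phosphate and sulphate supply were higher than in control. miR397, which targets laccases, was at 4.64 RPM in control and 37.9 at 5 d, 8.18-fold higher (log2 ratio 3.03, 95% interval 2.70 to 3.38). All 3 copper families were at least 2-fold higher, with a median log2 ratio of 1.57 at percentile 97.3 of random lists; miR398 was at 1.57 and miR408 at 1.42. Of the 4 phosphate and sulphate families 3 were at least 2-fold higher, with a median of 1.27 at percentile 97.5. miR395, which targets ATP sulfurylases, was at 1.82 (95% interval 1.32 to 2.35), miR2111 at 1.32, miR399, which targets the PHO2 ubiquitin-conjugating enzyme, at 1.21, and miR827 within 2-fold at 0.46.

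In all, 7 of 34 families were at least 2-fold higher at 5 d and 2 lower, and the same 9 passed under each other scaling tried. The seventh higher family was miR477, 3.27-fold above control (log2 ratio 1.71, 95% interval 1.54 to 1.88), but at 0.33 with at most 2 mismatches. miR390 was 4.48-fold lower (log2 ratio -2.17, 95% interval -2.23 to -2.10), its passenger strand 3.88-fold and the TAS3 tasiRNAs 2.11-fold lower, from 785 to 372 RPM. miR394 was 3.16-fold lower on 100 and 42 reads (log2 ratio -1.66, 95% interval -2.22 to -1.13). With exact matches miR399 was at 0.97, under the 2-fold size. The passenger strand of miR408 had 2 reads in control and 43 at 5 d, a log2 ratio of 4.02 with a 95% interval of 2.08 to 7.11.

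**Figure D2:**
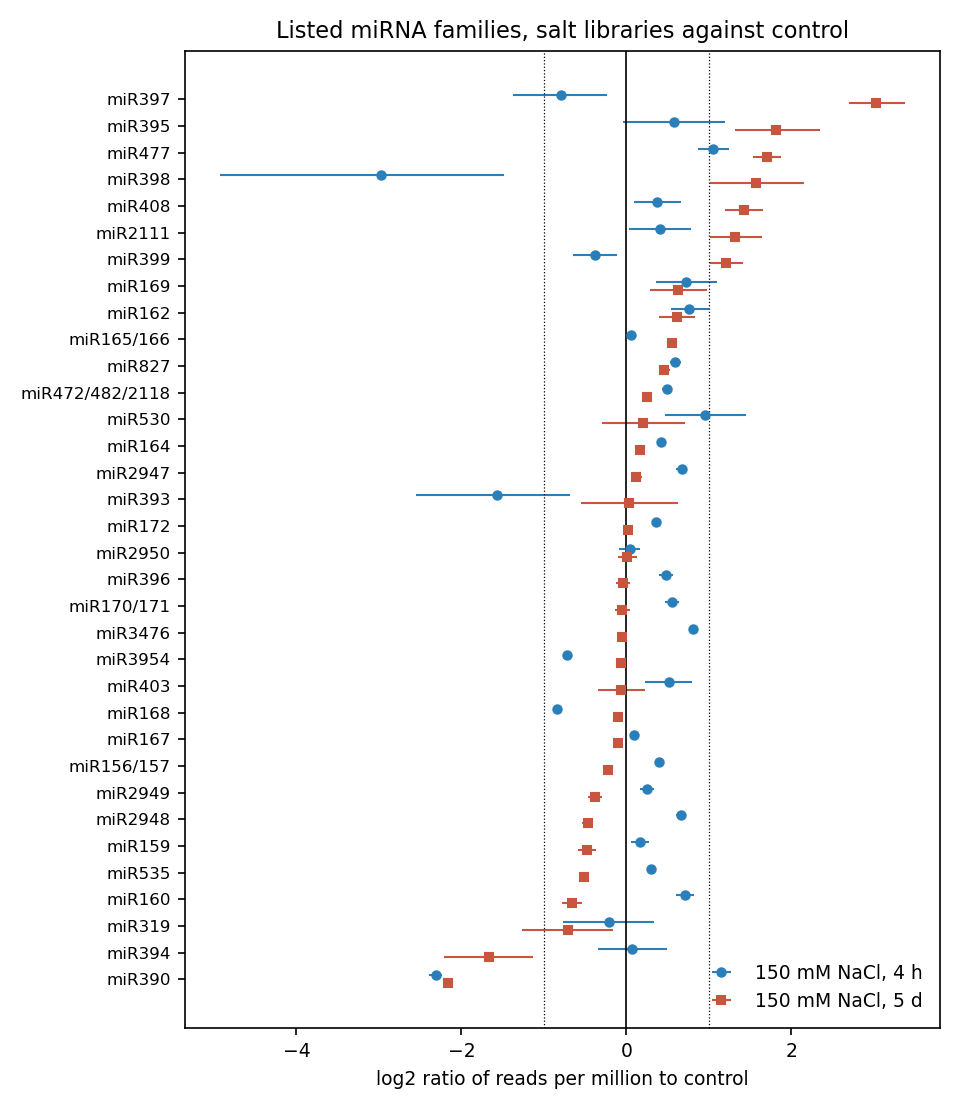
Log2 ratio of RPM to control on the x axis for the miRNA families on the y axis with at least 100 reads over 2 libraries in at least 1 comparison; circles are the 4 h library, squares the 5 d library, bars the 95% interval of counting error, and dotted lines mark 2-fold. miR390 lies at -2.31 and -2.17 in the salt libraries, and miR397 at -0.80 and 3.03.

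The other groups stayed mostly within 2-fold at 5 d. All 8 families of phase and leaf development did so, with a median log2 ratio of -0.05. miR165/miR166 was at 0.55 and its passenger strand at 0.68, whereas the uncounted miR166 form with a shifted 5′ end was at -0.40. miR156/miR157 was at -0.22, but its members parted. The leading miR157 sequence was at -0.29 and the listed miR156 sequence at 0.69, while the uncounted miR156 form was at -0.40. In the auxin group 1 of 4 families, miR390, was lower and the median was -0.38; miR160 was at -0.66. The small RNA machinery had 3 of 3 families within 2-fold and a median of -0.06, with miR162 at 0.61. The NF-Y and F-box group had 1 of 3 families lower, miR394, and a median of 0.03, with miR169 at 0.63. The 2 measured MYB families were within 2-fold, with a median of -0.11 and miR159 at -0.48. The 7 cotton families were within 2-fold, with a median of -0.06 and miR2948 at -0.47. Of the other conserved families 1 of 3 was higher, with a median of 0.20 and miR535 at -0.51, and miR472/miR482/miR2118 was at 0.26, but at 1.58 and thus at least 2-fold higher with exact matches. The ratios of miR3954, miR167, miR168 and miR3476 were between -0.10 and -0.05 and changed sign per total of listed family reads. With exact matches to the listed sequence miR3954 was at -0.62, while its leading cotton sequence was at -0.06.

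**Figure D3:**
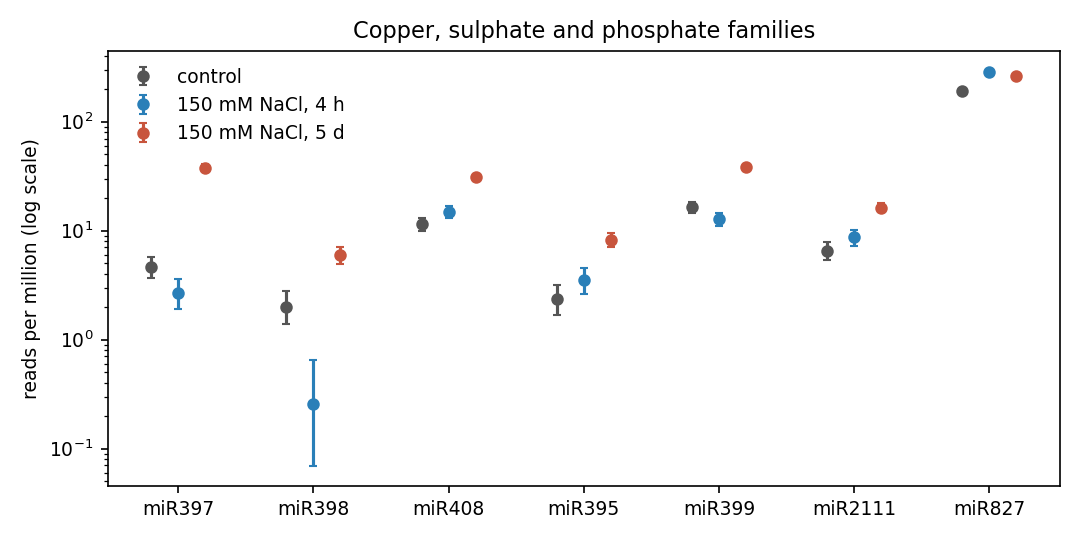
RPM on a log axis for 7 miRNA families of copper, sulphate and phosphate supply on the x axis; each point is 1 library and bars are the 95% interval of counting error. miR397 lies at 4.64, 2.67 and 37.9 RPM in the control, 4 h and 5 d libraries.

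The 5 d library also stood apart from the other libraries in features that do not depend on miRNA level. The share of the substitution T1G, with positions counted from 1 at the 5′ end of the read, had a median over 8 abundant sequences of 0.838% in control, 0.832% at 4 h and 0.0447% at 5 d. Reads over 32 nt were at 55.6, 66.3 and 3.23 RPM. Whether it was sequenced or processed separately was not determined. The 5 d group is this library alone, so any such difference and the salt treatment cannot be told apart.

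Among 1019 abundant sequences, 250 were at least 2-fold higher at 5 d and 192 lower. Fragments of rRNA, a class partly chosen by outcome, made up 350 of these sequences, of which 123 were higher and 84 lower. Of 62 1-base variants 1 was higher and 32 were lower, and of 37 sequences of listed miRNA families 0 were higher and 1 lower. The 538 sequences in no class had 120 higher and 69 lower. The lowest ratios all belonged to 1-base variants of far more abundant sequences. TGGGATGTAGCTCAGATGGT (G1T of a tRNA-Ala fragment) was 29.4-fold lower, GTGACAGAAGATAGAGAGCAC (T1G of miR157) 22.1-fold, GTGGACAGAGTAATCACGGTCG (T1G of miR3954) 21.04-fold, TTGACAGAAGAAAGAGAGCAC (T12A of miR157) 18.5-fold and TTGACAGAAGATAGAGAACAC (G18A of miR157) 17.2-fold lower. The highest was a 23-nt sequence in none of the sets used here, with 10 reads in control, 48 at 4 h and 19561 at 5 d. The next were 18S rRNA fragments, TAACTCGACGGATCGCACGG (14.0-fold) and CAGACTGTGAAACTGCGAATGGC (10.7-fold), and 25S rRNA fragments, AACGGGCTTGGCAGAATCAGCGGGG (9.24-fold) and ACGGGCTTGGCAGAATCAGCGGGG (8.82-fold).

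Compared with 4 h directly, the 5 d library had 5 of 33 families at least 2-fold higher, miR398, miR397, miR399, miR395 and miR408, and 3 lower, miR394, miR160 and miR2948. miR398 had a log2 ratio of 4.54 (95% interval 3.15 to 6.44, 4 and 134 reads) and miR397 one of 3.83 (3.38 to 4.31). miR399 was at 1.59, miR394 at -1.73 and miR160 at -1.37. The median log2 ratio of the families was -0.23, and centred on it miR2948 was no longer 2-fold lower. Per total of listed family reads, miR160 was at -0.97.

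The 1 family called higher and the 1 called lower at 4 h, miR477 and miR390, were called in the same direction at 5 d. Among the 31 families tested in both comparisons, with 1 higher at 4 h and 5 at 5 d and with 1 and 2 lower, independent lists of these sizes would share 0.161 higher and 0.0645 lower families, and 1000 simulations of unchanged libraries against the same control gave an overlap of 0, with counting error as the only variation. Both comparisons used the same control library, so part of the overlap may lie in that library, and miR477 was not shared when centred on the median family.

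Families that cotton is not known to make gave the background level. miR158, known from Brassicaceae, was at 15.2, 83.8 and 8.63 RPM as the exact sequence, and miR173 at 0.470, 4.26 and 0.398. The animal miRNA let-7 was at 2.17, 1.53 and 1.86 RPM as the exact sequence and at 18.7, 10.5 and 8.63 with at most 1 mismatch, and miR-21 and miR-122 had at most 9 reads in any library. miR161 and miR528 had at most 7 reads, and miR163, miR444 and miR-16 had 0 in each library, which allows up to 0.191 RPM. Of the 39 families, 17 in control, 20 at 4 h and 11 at 5 d lay below the level of the exact miR158 sequence. Those below it in each library were miR319, miR393, miR394, miR395, miR398, miR479, miR530, miR828, miR845, miR858 and miR3627, with miR398 at 2.00, 0.254 and 5.93 RPM and miR395 at 2.35, 3.50 and 8.28, the last within counting error of it. The control levels of miR397 (4.64), miR2111 (6.52) and miR408 (11.5), against which their 5 d ratios were taken, also lay below it, as did the 4 h levels of miR477 (42.7), the family called higher there, and miR399 (12.6). With at most 1 mismatch, the rule used for the families, miR158 was at 16.6, 93.5 and 9.21 RPM. The control level of miR399 (16.4) was then below it as well. The passenger strands of miR164, miR398 and miR399 also had 0 reads, those of miR170/miR171 and miR319 at most 12, and the others lay between 0.0587 and 219 RPM.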

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

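All tests of explanations in this part were chosen after the results were seen, and those on rRNA and tRNA sizes, on the leading miR398 sequence, on rare families and on the number of copper, phosphate and sulphate families replaced first forms whose outcome was known.

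The families miR397, miR398 and miR399 differed in direction between the salt libraries. miR397 had a log2 ratio to control of -0.80 at 4 h and 3.03 at 5 d, miR398 -2.97 and 1.57, and miR399 -0.38 and 1.21, opposite directions whose difference was not tested against replicates. The other copper, phosphate and sulphate families were above control in both when scaled to the file total: miR408 was at 0.38 and 1.42, miR2111 at 0.41 and 1.32, miR395 at 0.57 and 1.82 and miR827 at 0.59 and 0.46, of which the 4 h values of miR408 and miR2111 did not exceed the median family at 0.41. A like rise of all rare families through depth or scaling is argued against by 10 other families under 50 RPM in control, of which 8 had intervals below 1.01, the lowest interval bound among miR395, miR397, miR398, miR399, miR408 and miR2111. The 10 leave out miR479, miR828 and miR845, also under 50 RPM, which had at most 7 reads in any library. Their intervals were too wide to tell, with upper bounds of 5.89, 6.47 and 2.49. A rise of some rare families through the sequencing run stays open, since the 10 ranged from -1.66 to 1.71, the highest being miR477. Sequencing errors that add reads with a mismatch at 5 d are argued against by exact matches of miR395, miR397, miR399, miR408 and miR2111, lowest at 0.97. That check does not cover exact matches lost in control, where the T1G substitution was more frequent. For miR398 exact matches were too few (2 and 9 reads), and its leading sequence, at 2.51, was used instead. That sequence was picked by its total reads, which were 15 in control, 3 at 4 h and 113 at 5 d. Its 5 d ratio is therefore partly built into the choice and does not decide the question for miR398. The whole family had 34 reads in control and 134 at 5 d. Reads of a Brassicaceae plant are argued against by miR158 at -0.82. That 6 of the 7 listed families, all but miR827, were at least 2-fold higher may reflect 5 d of salt. However, 1 library per group, the stepwise salt, a possible difference in seedling age and the separate character of that library leave it open.

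The 24-nt share was lower at 4 h than in control. Without miR156/miR157 reads it was still 0.612 of control, so the dominance of that family does not account for it. Recovery of shorter RNA pieces stays open: the 24-nt share was 0.492 of control in rRNA fragments, 0.565 without the last 2 seeds, 0.597 without 5.8S rRNA and 0.735 in the rRNA listed beforehand, and 0.491 in tRNA fragments and 0.670 in the tRNA listed beforehand. The ratio of 24-nt to 21-nt reads was 0.434, 0.529 (the first form of the test, which on its own had gone with this explanation), 0.509 and 0.870 of control in the same rRNA sets, and 1.06 and 1.34 in the tRNA sets. A fall of 24-nt siRNAs with salt beyond rRNA also stays open, since the 24-nt share of the other reads relative to the same 4 rRNA sets was 1.28, 1.11, 1.05 and 0.855 and their 24-to-21-nt ratio 1.04, 0.858, 0.891 and 0.521. Both measures were above 1 with the widest set alone, whose last seeds were picked among the sequences lowest and highest at 4 h, and they parted in the next 2 and were below 1 with the listed rRNA.

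The 5 d library held 25 sequences at least 100-fold above both other libraries, with 28975 reads, against 2 in control and 0 at 4 h. Reads with an animal 5.8S rRNA motif were at 18.1 RPM at 5 d, a log2 ratio of 4.69 to control, so some of the 25 may come from another organism, although the motif does not tie them to it. Of the 25, 24 were in no miRNA, rRNA, tRNA or U6 set, and without a genome cotton transcripts stay open for these.

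The background miRNAs miR158 and miR173 were at 83.8 and 4.26 RPM at 4 h, above 15.2 and 0.470 in control. Whether reads of a Brassicaceae plant also entered the listed families or passenger strands at 4 h was not tested.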

How the results depend on the processing

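Alternatives were fixed before the data were examined, except those for the overlap of families, those that leave out miR156/miR157, rRNA, tRNA and U6 reads or keep only the other reads, and the sets of rRNA and tRNA, which were chosen after seeing the data; where a value below moved, the cause was not tested. No family called at least 2-fold apart when scaled to the file total with at most 1 mismatch had its sign reversed in a scaling or matching alternative run on it. miR3954, not called so at 4 h, was at -1.13 by the median of ratios and 0.45 with exact matches. Leaving out settings that could not move a value (the stated totals, and a minimum count that removed no family), 66 of 130 alternative ratios of single families stayed within the counting interval at 4 h, 81 of 128 at 5 d and 21 of 27 between the salt libraries; 4 of 26 and 9 of 22 alternative group medians, at 4 h and 5 d, moved by no more than the counting error of the group's summed reads, a narrow tolerance set mostly by its most abundant family. No paired analysis was possible because each group had 1 library. Depth limits families with few reads, such as miR398 with 4 reads at 4 h.

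The 1 family higher at 4 h became 0 per total of listed family reads, 0 by the median of ratios, 0 with 2 mismatches, 0 with full-length matches and 0 at 4-fold, and 2 at a minimum of 10 reads and 2 without the 10 most abundant sequences. The 1 lower at 4 h became 3 per total of listed family reads, 4 by the median of ratios and 3 at a minimum of 10 reads. The 7 higher at 5 d became 6 with exact matches (5 of them shared; miR398 and miR399 were lost and miR472/miR482/miR2118 gained), 6 with 2 mismatches (miR477 lost), 5 with full-length matches (4 shared), 2 at a minimum of 1000 reads and 1 at 4-fold. The 2 lower at 5 d became 3 with 2 mismatches (miR3627 gained), 1 with full-length matches, 1 at a minimum of 1000 reads and 1 at 4-fold. Between the salt libraries the 5 higher became 9 per total of listed family reads, 3 with full-length matches, 1 at a minimum of 1000 reads, 2 at 4-fold and 3 without the 10 most abundant sequences, and the 3 lower became 1 per total of listed family reads, 5 at a minimum of 10 reads, 0 at 4-fold and 6 without the 10 most abundant sequences. The 1 family higher in both salt libraries became 0 per total of listed family reads, 0 by the median of ratios, 0 with 2 mismatches, 0 with full-length matches and 0 at 4-fold; the 1 lower in both stayed at 1.

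At 10 RPM, 200 RPM and 4-fold, the sequences higher at 4 h numbered 1492, 80 and 257, those lower 1238, 56 and 124, those higher at 5 d 1235, 30 and 104, and those lower 780, 56 and 59. The 24-nt share was below control at 4 h in every alternative. In the control, 4 h and 5 d libraries it was 59.2%, 45.0% and 57.6% of distinct sequences, 16.5%, 7.71% and 18.5% for sequences with at least 2 reads, 39.0%, 23.8% and 39.3% without the 10 most abundant, 34.7%, 21.2% and 35.0% without miR156/miR157, 27.01%, 14.7% and 28.7% without rRNA, tRNA and U6, and 44.3%, 27.8% and 44.2% for the other reads alone. The 21-nt share was 9.15%, 14.6% and 8.60% of distinct sequences, 50.1%, 59.0% and 44.8% for sequences with at least 2 reads, 20.6%, 26.95% and 19.4% without the 10 most abundant, 22.3%, 29.4% and 21.4% without miR156/miR157, 44.4%, 56.2% and 38.9% without rRNA, tRNA and U6, and 21.3%, 29.6% and 19.02% for the other reads alone. At 5 d the 24-nt share was above control in 4 of the 6 alternatives and below it among distinct sequences and among the other reads alone.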

Other observations

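Several abundant small RNAs, all but the last outside the listed families, also differed between libraries, each chosen after its values were seen. TTTGCATGAACTAGGAGACGT, a 21-nt sequence in none of the sets, was at 8789 RPM in control, 10941 at 4 h and 4091 at 5 d. TTCCCAAAACCTCCAATTCCAA was 3.04-fold higher at 4 h and 4.68-fold higher at 5 d than in control, from 49.1 RPM. CAGAGATCGTCAAAGCATATC was at 557.4, 180 and 815 RPM. The 18-nt tRNA-Gly fragment GCGTTTGTAGTCCAACGG was at 3063, 3913 and 631 RPM, and the listed miR156 sequence TGACAGAAGAGAGTGAGCAC at 15966, 23499 and 25693.

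Guide and passenger strands did not always differ in the same direction. miR168 was 1.79-fold lower at 4 h while its passenger strand was 1.75-fold higher, and at 5 d both were within 1.07-fold of control. miR390 and its passenger strand were lower in both salt libraries, whereas the TAS3 tasiRNAs were lower at 5 d alone, at 785, 806 and 372 RPM in the control, 4 h and 5 d libraries.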
